A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

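Swc4 carrying a Myc tag was measured by ChIP-seq with an antibody against c-Myc in Saccharomyces cerevisiae. Cells were grown at 30 °C in 50 ml of rich medium to an OD600 of about 0.6 and sonicated. The 10 samples formed 5 groups of 2 repeats. The deposited peak lists, 4 in number, each pool both repeats of 1 tagged group per the labels, and no list was used for the untagged strain. Per the submitters' processing notes, reads were trimmed with fastp 0.21.0, aligned with BWA 0.7.15-r1140 and sorted with SAMtools 1.4, and peaks were called with MACS2. The genome build, the control used for the calls and the MACS2 settings are not given in the sources used here.

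The deposited lists give for each peak its chromosome, start, end, summit and values from the authors' peak calling. The fold enrichment is the authors' ratio of the pileup at the summit to the local background. The significance is the authors' −log10 p and −log10 q at the summit, where q is p adjusted by MACS2. The deposited score is 10 times −log10 q, without decimals, and was not used. The smallest −log10 q was 1.31 in each list, just above that of q 0.05.

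The assembly R64 of the gene table was set against the peaks, since the build is not given. Within 60 bp of the middle of a tRNA gene lay a summit for 34 of 275 genes in wild type, 114 in yaf9Δ, 76 in eaf1Δ and 113 in swr1Δ, and when the summits were shifted by 100 to 1000 bp it was 1 to 16. The table held 275 nuclear tRNA genes, 6002 nuclear protein-coding genes with a strand and 82 snRNA or snoRNA genes. The promoter was the 500 bp upstream of the annotated start of the gene. A tRNA, snRNA or snoRNA gene had a peak when a peak overlapped the gene extended by 100 bp. A chromosome end was the outermost 10 kb of an arm. Chromosome lengths were not used, so the right end was the furthest end of a gene or of a peak in any list. Each peak was also given 1 class by its summit, in the order rDNA, tRNA gene, chromosome end, ribosomal protein promoter, other promoter, gene body and elsewhere.

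Within each list, the number of nuclear peaks at a feature was compared with 10000 random placements of the same peaks, with chromosome and width kept (1-sided permutation test, Benjamini-Hochberg adjustment over features and lists). Promoters of each gene list were compared with those of all other protein-coding genes by 2-sided Fisher's exact test, adjusted over 76 tests. There were 20 gene lists, of which 19 were tested at promoters and that of other RNA polymerase III genes was described gene by gene, and 1 listed gene was not in the gene table. A wild-type peak had a counterpart when at least 1 bp lay in a mutant peak, and the expected share came from 10000 random placements of the mutant peaks. Shares carry exact Clopper-Pearson 95% intervals. Genotypes were not tested against each other, since each has 1 pooled list. Counts expected for independent lists are the product of the 2 counts divided by the total.

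The depth per sample is not given in the sources used here. Where −log10 p was at most 250, the pileup and local background at a summit were solved from fold and −log10 p with the Poisson formula of MACS2, which adds 1 to both when it forms the fold. The pileup came out whole within 0.05 at 97.9% of solved summits in wild type, 99.8% in yaf9Δ, 99.6% in eaf1Δ and 98.3% in swr1Δ, and at 9.40% to 11.0% when −log10 p was perturbed. The lowest local background among summits of whole pileup was taken as the background pileup of the list. If MACS2 ran with its default minimum length, no peak is shorter than its fragment length, and the shortest peak was taken as that length. The settings are not given, so this default was not checked. The ratio of background pileup to shortest peak gave fragments per base of 1.81 in yaf9Δ, 1.53 in eaf1Δ and 1.27 in swr1Δ relative to wild type.

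Features, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except the placement test of summits in gene bodies, the tests for fewer peaks, the shares of gene bodies by rank and the window of 1 kb at chromosome ends, which were added after the data were seen. The rule named YAF9, EAF1, SWR1 and SWC4, the 10 peaks of highest −log10 q in each list, per mutant the 10 peaks of highest fold without a wild-type peak and the 10 wild-type peaks of highest fold without a counterpart, the 10 wild-type peaks of highest fold with a counterpart in all 3 mutants, and up to 4 members of each gene list. A peak took the tRNA gene within 100 bp of its summit, else the gene whose promoter or body held the summit, else the gene of nearest start. The text gives a part of these.

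Alternatives were −log10 q of at least 5, fold of at least 2, equal list length by −log10 q, merging peaks under 200 bp apart, tRNA windows of 0 and 500 bp, ends of 5 and 20 kb, promoters of 250 and 1000 bp, summits in place of peaks, overlap of 50% of the shorter peak, summits at most 100 bp apart, placement outside protein-coding genes, and leaving out rDNA and mitochondrial peaks. A common background scale was added after the data were seen, as were the alternatives for gene bodies, snRNA and snoRNA genes and shared ribosomal protein promoters. Mitochondrial peaks were left out of the placement tests. The tests were tested on simulated data. Of 100 random lists 6 were called with the size of wild type, 5 with that of yaf9Δ, 2 with eaf1Δ and 4 with swr1Δ, and 50 of 50 implanted peaks were recovered in each. The implanted peaks were set on tRNA genes and counted there, so their recovery was fixed by construction and checks only the counting. The random lists came from the same placement as the test, so they do not cover clustered peaks. A simulated odds ratio of 1 was called in 1 of 100 runs and of 4 in 100 of 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.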

Results

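Chromatin immunoprecipitation and sequencing (ChIP-seq) mapped Myc-tagged Swc4 on the chromatin of budding yeast growing in mid-log phase at 30 °C. Swc4 is shared by SWR1, the complex that places the histone variant H2A.Z in nucleosomes, and NuA4, a histone acetyltransferase. The 10 samples formed 5 groups of 2 repeats, namely wild type, yaf9Δ, eaf1Δ and swr1Δ with tagged Swc4, and wild type with no tag. Yaf9 is another shared subunit, Eaf1 is the scaffold of NuA4 and Swr1 is the ATPase of SWR1. There were 4 peak lists, and each pools both repeats of a tagged group, so there is no replicate spread and no test between genotypes. The untagged samples were not analysed here, and whether they served as the control of the peak calls is not given in the sources used here. Unspecific signal was therefore not measured, and bound means below only that a peak was called.

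The lists held 625 peaks in wild type, 4590 in yaf9Δ, 2937 in eaf1Δ and 1262 in swr1Δ, which covered 3.34%, 18.4%, 13.9% and 5.12% of the nuclear genome. Median peak width was 558 bp in wild type, 366 bp in yaf9Δ, 449 bp in eaf1Δ and 412 bp in swr1Δ. The read totals are not given in the sources used here. The background pileup, recovered from the peak values as fragments per position, was 59.4 in wild type, 59.6 in yaf9Δ, 64.3 in eaf1Δ and 54.4 in swr1Δ. The shortest peak was 351 bp in wild type, 195 bp in yaf9Δ, 249 bp in eaf1Δ and 252 bp in swr1Δ. Folds below are the peak caller's, over its own background, and serve to rank peaks within a list, not to compare lists. Intervals are exact 95% intervals and cover counting error only. The genome build is not given in the sources used here, and coordinates are those of the peaks.

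In wild-type cells the most significant Swc4 peaks lay near chromosome ends, in the rDNA and at promoters of ribosomal protein genes. The peak of highest significance was beside YHR219W near the right end of chromosome VIII (562178–562625, fold 4.80). Next came peaks near the left end of chromosome XII, beside YLL066C (10952–11853, fold 4.94) and at YLL066W-B (5431–5949, fold 7.99), and then the rDNA. The fold of the rDNA peak was 1.57, below the median of the list (1.67). Significance rises with the pileup as well as with fold, so this rank does not show strong enrichment in the rDNA. Promoters of the ribosomal protein genes RPS11B (chromosome II, 332363–332948, fold 7.47), RPL13B (chromosome XIII, 551189–552014, fold 6.08), RPS24A, RPS23A and RPL6A followed, with the peak beside GPC1, a gene of phospholipid metabolism, which also overlaps the promoter of the ribosomal protein gene RPL24B. By the place of their summits, each counted once, the 625 wild-type peaks divided into 1 in the rDNA, 37 at tRNA genes, 23 in the last 10 kb of a chromosome, 54 at ribosomal protein promoters, 170 at other promoters, 288 in gene bodies outside all of these, and 52 elsewhere. Reads from repeated sequence at chromosome ends, tRNA genes and the rDNA can be shared between copies, so which copy was bound is uncertain there.

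tRNA genes, 1 of the 3 kinds of locus in the series title, had peaks in every list. A peak lay within 100 bp of 62 of the 275 nuclear tRNA genes in wild type (22.5%, interval 17.7–27.9), 151 in yaf9Δ (54.9%, 48.8–60.9), 112 in eaf1Δ (40.7%, 34.9–46.8) and 140 in swr1Δ (50.9%, 44.8–57.0). With peaks of fold at least 2 it was 35 in wild type, 141 in yaf9Δ, 102 in eaf1Δ and 136 in swr1Δ. The yaf9Δ list held 62 of the 62 wild-type tRNA genes, the swr1Δ list 60 and the eaf1Δ list 54, where independent lists would share 34.0, 31.6 and 25.3. In all 4 lists 54 tRNA genes had a peak, 53 had one in all 3 mutants and not in wild type, and 116 had none. SUF8 and IMT1, an initiator methionine tRNA gene, had no wild-type peak and were among the strongest of those in yaf9Δ (folds 6.01 and 5.44) and in eaf1Δ (4.86 and 4.21), and SUF8 also in swr1Δ (5.89). YNCG0002C and YNCP0024C, named after their values were seen, were the tRNA genes with a wild-type peak and none in swr1Δ, and both also lacked a peak in eaf1Δ.

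Each list had more peaks at tRNA genes than the same peaks placed at random on their chromosomes. Wild type had 56 against a mean of 13.0 (ratio 4.29), yaf9Δ 145 against 78.2 (1.86), eaf1Δ 106 against 55.8 (1.90) and swr1Δ 134 against 21.9 (6.11). The 1-sided permutation p was 0.0001 in each, the smallest the 10000 placements can give, and 0.0002 after adjustment over features and lists. With summits placed only outside protein-coding genes the ratio turned to 0.612 in yaf9Δ and 0.649 in eaf1Δ, and fell to 1.48 in wild type and 2.01 in swr1Δ. That placement raises the random count at tRNA genes by construction. It moves peaks out of gene bodies, where 84.5% of yaf9Δ and 82.9% of eaf1Δ summits lay. The turned ratios therefore do not show a lack of peaks at tRNA genes.

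Other genes of RNA polymerase III had peaks too. SCR1, the RNA of the signal recognition particle, had a peak in all 4 lists, with a fold of 2.93 in wild type, 5.53 in yaf9Δ, 3.09 in eaf1Δ and 3.70 in swr1Δ. RPR1, the RNA of nuclear RNase P, also had a peak in all 4 lists, with a fold of 2.42 in wild type. RNA170 had a peak in wild type, yaf9Δ and eaf1Δ (folds 1.38, 1.46 and 1.46). SNR52, a snoRNA gene, had a peak in yaf9Δ (fold 3.04) and swr1Δ (3.63), and SNR6, the U6 snRNA gene, had none in any list.

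**Figure D1:**
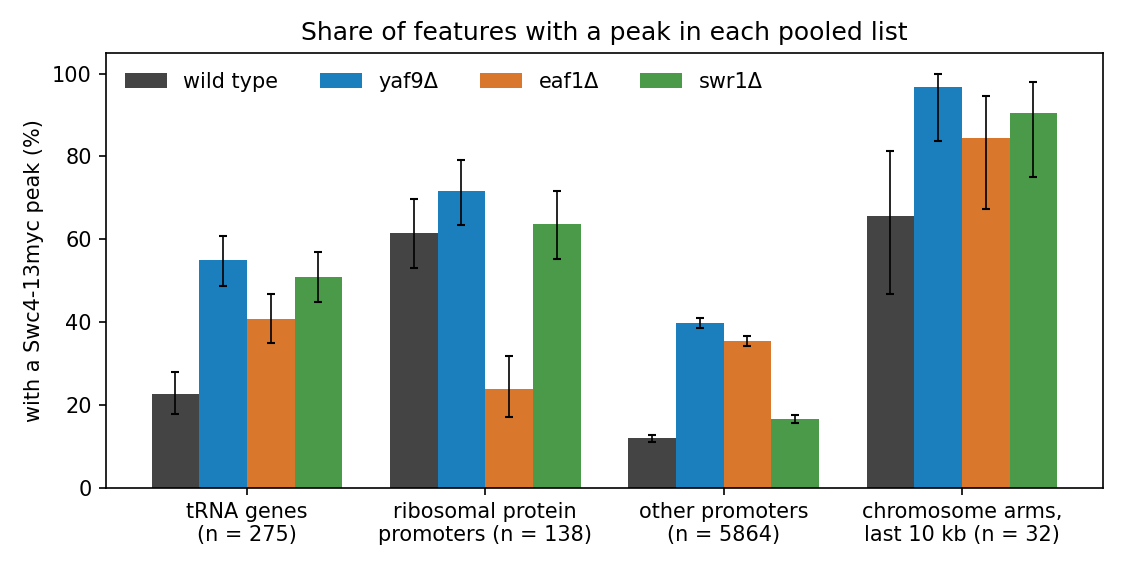
Bars give the percentage of 275 tRNA genes, 138 ribosomal protein promoters, 5864 other protein-coding promoters and 32 chromosome arms (last 10 kb) with a Swc4 peak in each of the 4 lists, and error bars are exact 95% intervals for counting error. Ribosomal protein promoters stood at 61.6% in wild type, 71.7% in yaf9Δ, 23.9% in eaf1Δ and 63.8% in swr1Δ, while tRNA genes stood at 22.5%, 54.9%, 40.7% and 50.9%.

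In the rDNA, Swc4 formed a peak between RDN37-1 and RDN25-2 over RDN5-1, a 5S rRNA gene, and ETS2-2, the downstream external spacer. It lay at 459592–460742 of chromosome XII in wild type (fold 1.57, −log10 q 261, rank 4), 459496–460833 in yaf9Δ (fold 4.28, −log10 q 4733), 459499–460824 in eaf1Δ (3.09, 2844) and 459589–460773 in swr1Δ (2.85, 1804). In the 3 mutants it was the peak of rank 1. Its summit lay in no gene body or promoter in any list, at 460554 in wild type and swr1Δ, 460206 in yaf9Δ and 460204 in eaf1Δ. A further peak lay at the 5S gene RDN5-2 in yaf9Δ (468723–469007, fold 3.22) and eaf1Δ (468712–469014, fold 3.02). The 5S gene RDN5-6, outside the main array, was overlapped by a peak in every list, at 489298–490581 in wild type (fold 1.64) and 489271–490019 in swr1Δ (fold 3.78). The summit of that peak was at 489916 in wild type and 489913 in eaf1Δ, and at 489466 in yaf9Δ and swr1Δ. The repeats are collapsed in the reference, so no random expectation was computed for them.

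Most chromosome arms had a Swc4 peak near their end. No random expectation was computed for the number of arms, and a longer list reaches more arms at random. A peak lay in the last 10 kb of 21 of the 32 arms in wild type (65.6%, interval 46.8–81.4), 31 in yaf9Δ (96.9%), 27 in eaf1Δ (84.4%) and 29 in swr1Δ (90.6%). In the last 1 kb it was 10 arms in wild type, 21 in yaf9Δ, 17 in eaf1Δ and 19 in swr1Δ. On right arms a peak that reached past the last gene could itself set the end, and was then counted by construction. In all 4 lists 20 arms had a peak in the last 10 kb. The left end of chromosome III, beside YCL075W, had a peak in yaf9Δ (7–991, fold 5.07), eaf1Δ (29–992, fold 3.34) and swr1Δ (8–1014, fold 5.91), and no wild-type peak. Beside YNR077C at the right end of chromosome XIV, yaf9Δ (783472–784325, fold 4.34), eaf1Δ (783883–784315, fold 3.26) and swr1Δ (783441–784326, fold 6.18) had a peak and wild type had none. The left arm of chromosome XVI, named after its values were seen, had none in any list.

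As a class, chromosome ends did not pass the placement test for more peaks in any full list, and the call depended on the setting. There were 23 peaks against 16.8 in wild type (ratio 1.37, 1-sided permutation p = 0.078), 43 against 34.5 in swr1Δ (p = 0.086), 68 against 80.3 in eaf1Δ (0.846, p = 0.93) and 75 against 121 in yaf9Δ (0.618, with p = 0.0001 for fewer). Peaks of fold at least 2 gave 3.49 in wild type and 2.53 in swr1Δ (permutation p = 0.0001 each), and −log10 q of at least 5 gave 1.68 (p = 0.014) and 1.57 (p = 0.0049), while a window of 20 kb gave 0.835 and 0.855. With lists of equal length swr1Δ passed (1.87, permutation p = 0.0008), the yaf9Δ ratio turned to 1.53 (p = 0.026) and that of eaf1Δ to 1.28 (p = 0.15), and a window of 5 kb gave 1.62 in swr1Δ (p = 0.009).

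Promoters held peaks more often than random placement in every list. In wild type 485 peaks (77.6%) overlapped the 500 bp upstream of a protein-coding gene, against 269 at random (ratio 1.80), and in swr1Δ 744 (59.1%) against 479 (1.55). In eaf1Δ it was 1557 (53.7%) against 1172 (1.33), and in yaf9Δ 1912 (42.3%) against 1709 (1.12). Each had a 1-sided permutation p of 0.0001, the smallest possible. When the summit had to lie in the promoter the ratio was 0.837 in yaf9Δ and 1.02 in eaf1Δ (permutation p = 0.25). Promoters of 250 bp also reversed yaf9Δ. Placement outside protein-coding genes turned the 3 mutants, to 0.622 in yaf9Δ, 0.778 in eaf1Δ and 0.872 in swr1Δ, but it raises the random count in promoters by construction.

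Gene bodies took most of the summits in the yaf9Δ and eaf1Δ lists, by a placement test that was added after the data were seen and that counts every summit in a gene body, also those in a promoter or at another feature. Summits lay in a gene body for 391 peaks in wild type (62.6%) and 738 in swr1Δ (58.7%), fewer than the 72.9% and 72.7% at random (1-sided permutation p = 0.0001 for fewer). In yaf9Δ it was 3823 (84.5%) and in eaf1Δ 2403 (82.9%), more than at random (permutation p = 0.0001). Among the 125 peaks of highest significance, gene bodies made up 20.8% in wild type (interval 14.1–29.0), 10.4% in yaf9Δ (5.65–17.1), 49.6% in eaf1Δ (40.5–58.7) and 6.40% in swr1Δ (2.80–12.2). Without peaks that overlap a ribosomal protein promoter, of which the first 125 held 59 in wild type and 0 in eaf1Δ, it was 40.0% in wild type (31.3–49.1), 24.0% in yaf9Δ, 49.6% in eaf1Δ and 13.6% in swr1Δ. In eaf1Δ those of highest significance included SED1 (chromosome IV, 600758–601893, fold 3.11) and CCW12 (chromosome XII, 369609–370146, fold 1.80), which encode cell wall proteins. The ratio to random was 1.16 in yaf9Δ and 1.14 in eaf1Δ and stayed above 1 with −log10 q of at least 5 (1.15 and 1.12, permutation p = 0.0001 each) and with peaks under 200 bp apart merged (1.16 and 1.14, p = 0.0001 each). With peaks of fold at least 2 it fell below 1 in yaf9Δ (0.936) and eaf1Δ (0.932), as it did with lists of equal length (0.593 and 0.843).

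**Figure D2:**
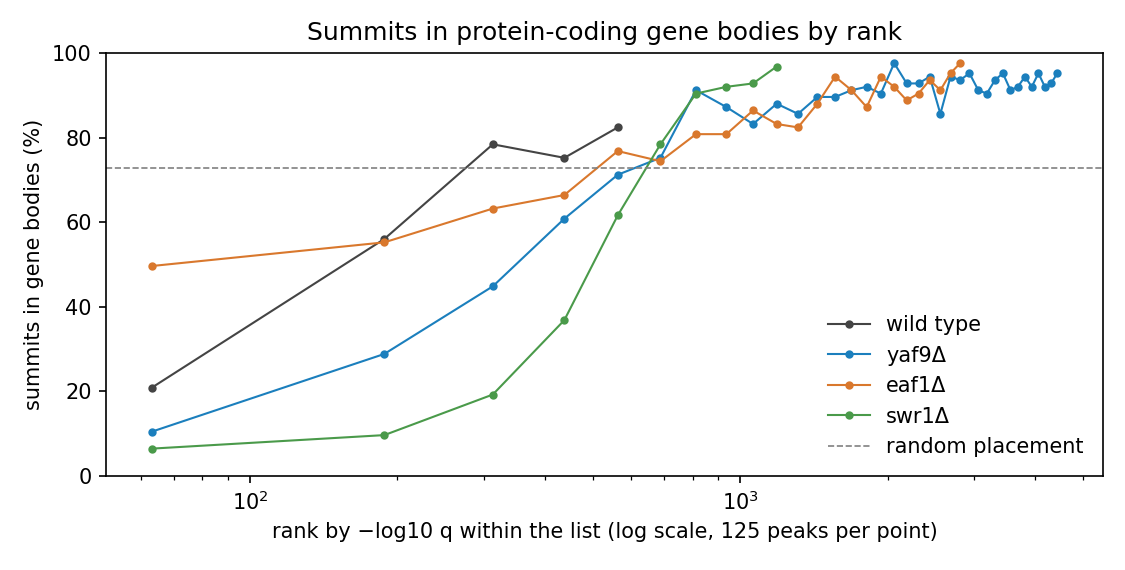
Lines give the percentage of peaks with a summit in a gene body (vertical axis) against the rank of the peaks by −log10 q (horizontal log axis) in each of the 4 lists, with 125 peaks per point, and the dashed line marks random placement. The first points stand at 20.8% in wild type, 10.4% in yaf9Δ, 49.6% in eaf1Δ and 6.40% in swr1Δ.

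snRNA and snoRNA genes had more wild-type peaks than random placement along the whole chromosome. Placement outside protein-coding genes was not run for them, so a general preference for places between genes cannot be told apart. There, 11 peaks lay within 100 bp of the 82 such genes against 3.85 at random (ratio 2.86, 1-sided permutation p = 0.0019, adjusted p = 0.0034). The mutant lists had 25 in yaf9Δ (ratio 1.03, permutation p = 0.47), 11 in eaf1Δ (0.655, p = 0.95) and 7 in swr1Δ (1.04, p = 0.51), and did not pass the test as full lists. In yaf9Δ the genes passed with lists of equal length (ratio 5.17, permutation p = 0.0001) and with fold at least 2 (1.91, p = 0.0085). The eaf1Δ ratio turned to 1.75 with lists of equal length (permutation p = 0.11).

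Ribosomal protein genes, which encode the proteins of both ribosomal subunits, were the group most often bound at the promoter in wild type among the 19 gene lists tested. Of 138 such promoters 85 had a wild-type peak (61.6%, interval 52.9–69.7), 99 a peak in yaf9Δ (71.7%, 63.5–79.1), 88 in swr1Δ (63.8%, 55.2–71.8) and 33 in eaf1Δ (23.9%, 17.1–31.9). Other protein-coding promoters had a peak in 11.9%, 39.8%, 16.6% and 35.5% of cases, in the same order. Of the 85 bound in wild type, yaf9Δ also had a peak at 84 (98.8%, lower bound 93.6), swr1Δ at 81 (95.3%, 88.4–98.7) and eaf1Δ at 26 (30.6%, 21.0–41.5). Over the alternatives the eaf1Δ share ranged from 4.71% at equal list length to 48.3% with promoters of 1000 bp, that of yaf9Δ from 96.5% to 100% and that of swr1Δ from 92.5% to 100%. The promoters with a peak in wild type, yaf9Δ and swr1Δ and none in eaf1Δ numbered 55, and 26 had a peak in all 4 lists. RPS23A had a fold of 7.21 in wild type and 12.5 in swr1Δ, where it led its group, and RPL13B led it in yaf9Δ with 13.1. In eaf1Δ the group was led by RPS0B with a fold of 2.85.

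By 2-sided Fisher's exact test against all other genes, the odds ratio of ribosomal protein promoters was 11.9 in wild type (adjusted p = 5e-40), 3.84 in yaf9Δ (2.4e-12), 8.85 in swr1Δ (1.7e-32) and 0.572 in eaf1Δ (0.045). The test counted a peak for every promoter it overlapped. RPL13B and RPS16A, for example, shared a wild-type peak, so promoters were not independent as the test takes them to be. By the same exact test the eaf1Δ call was lost with peaks of −log10 q at least 5 (0.630, adjusted p = 0.11), fold at least 2 (0.776, 0.94), promoters of 250 bp (0.696, 0.30) and of 1000 bp (0.782, 0.41). Among equal numbers of top-ranked peaks, 85 ribosomal protein promoters had a peak in wild type, 90 in yaf9Δ, 4 in eaf1Δ and 87 in swr1Δ.

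Cell wall and plasma membrane genes were also bound more often than other genes in each list. Peaks lay at the promoters of 7 of 17 members in wild type (odds ratio 4.71, Fisher's exact test, adjusted p = 0.045), 14 in yaf9Δ (6.89, 0.01), 14 in eaf1Δ (8.64, 0.0017) and 8 in swr1Δ (4.16, 0.045). Examples were CWP2, a cell wall mannoprotein (fold 2.35 in wild type, 6.36 in yaf9Δ and 5.93 in swr1Δ), SED1 (2.36 in wild type and 3.18 in eaf1Δ) and PMP3, a small membrane protein (1.60 in wild type and 3.42 in eaf1Δ). The wild-type call was lost at −log10 q of at least 5 (odds ratio 3.40, exact test, adjusted p = 0.14) and with 3 other settings, and the calls in yaf9Δ and swr1Δ were also lost with some. Histone genes passed in wild type, with 5 of 10 promoters (odds ratio 6.72, exact test, adjusted p = 0.045). Among them HTA1 and HTB1 shared 1 peak (fold 1.65), which the test counted for both genes, so the 5 promoters rest on fewer peaks. HTZ1, which encodes H2A.Z, had a fold of 1.55, and none of the 10 had a wild-type peak of fold at least 2.

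The remaining lists did not pass adjustment, and 9 of the 76 tests were called. Genes for SWR1 subunits had a promoter peak at 10 of 14 members in eaf1Δ (odds ratio 4.62, exact test, adjusted p = 0.064), among them VPS71 (fold 3.26). The galactose regulon, genes for use of that sugar, had a peak at 6 of 7 members in eaf1Δ (exact test, adjusted p = 0.064) and in yaf9Δ (0.09), at 1 in swr1Δ and at 0 in wild type. A peak between GAL1 and GAL10 had a fold of 3.22 in eaf1Δ (chromosome II, 278443–278820). Cyclins had a peak at 6 of 12 members in swr1Δ (exact test, adjusted p = 0.065), led by CLN2 (fold 7.07) and PCL1 (5.77), and glycolysis and fermentation at 8 of 19 (0.065). Ribosome biogenesis genes had a peak at 3 of 24 members in eaf1Δ (odds ratio 0.262, exact test, adjusted p = 0.09). The 4 genes of the silent mating cassettes had no promoter peak in any list.

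The question behind the yaf9Δ comparison is whether the place of Swc4 depends on Yaf9, another subunit that SWR1 and NuA4 share. Nearly every wild-type peak had a counterpart in yaf9Δ, 605 of 625 (96.8%, interval 95.1–98.0) against 34.2% for random placement of the yaf9Δ peaks. The strongest of the 20 wild-type peaks without one were at the SWR1 promoter (chromosome IV, 1135665–1136338, fold 3.24), RRP7, an rRNA processing gene (fold 2.85), and FUN12, a translation initiation factor gene (2.50). The yaf9Δ list added 3898 peaks with no wild-type counterpart (84.9%), of which, by the same classes, 3071 were in gene bodies outside the other places, 501 at other promoters, 79 at tRNA genes and 3 at ribosomal protein promoters. The strongest of these lay at BTN2, a protein sorting gene (fold 8.69), ISA1, of iron–sulfur cluster assembly (7.11), CSI2 (7.10), PDR5, a drug efflux pump (6.66), and HSP42, a small heat shock protein (6.57). The peaks of highest significance after the rDNA and YHR219W included ENV9 (chromosome XV, 795778–797367, fold 13.3, −log10 q 657) and YDR010C (chromosome IV, 464694–465602, −log10 q 679). No peak lay over YAF9 in any of the 4 lists, wild type included, and in yaf9Δ EAF1 carried peaks at 1192013–1192646 and 1194762–1195383.

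In eaf1Δ, where NuA4 lacks its scaffold, many ribosomal protein promoters bound by Swc4 in wild type had no counterpart peak while most other bound promoters had one. Of the 625 wild-type peaks 467 had a counterpart (74.7%, interval 71.1–78.1, against 25.2% at random). By class it was 36 of 37 at tRNA genes, 22 of 23 at chromosome ends, 27 of 54 at ribosomal protein promoters (50.0%, 36.1–63.9), 148 of 170 at other promoters (87.1%, 81.1–91.7) and 187 of 288 in gene bodies (64.9%, 59.1–70.4). Of the 10 strongest of the 158 wild-type peaks without a counterpart, all but that at YGL188C-A had their summit at ribosomal protein promoters, led by RPS11B (fold 7.47), RPL42B (5.89), RPS10A (5.29) and RPS21B (5.15). The eaf1Δ list added 2453 peaks (83.5%), of which, by the same classes, 1814 were in gene bodies outside the other places, 410 at other promoters, 47 at tRNA genes and 0 at ribosomal protein promoters. Among the strongest were RIM4, a meiotic RNA-binding protein (fold 4.87), HXT7, a hexose transporter (4.64), HXK1, a hexokinase (4.44), and MRPL23, a mitochondrial ribosomal protein (4.37). No peak lay over EAF1 in eaf1Δ, wild type or swr1Δ, and in eaf1Δ SWC4 carried a peak at chromosome VII, 499654–499967 (fold 2.76).

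In swr1Δ, which lacks the ATPase of SWR1, Swc4 peaks at tRNA genes, chromosome ends and ribosomal protein promoters had counterparts while many at other promoters and in gene bodies did not. Of the 625 wild-type peaks 406 had a counterpart (65.0%, interval 61.1–68.7, against 11.2% at random). By class it was 36 of 37 at tRNA genes, 22 of 23 at chromosome ends, 54 of 54 at ribosomal protein promoters, 96 of 170 at other promoters (56.5%, 48.7–64.0) and 151 of 288 in gene bodies (52.4%, 46.5–58.3). The classes were not matched for fold in swr1Δ. The median wild-type fold was 4.51 at ribosomal protein promoters and 2.01 at other promoters of their fold range. With fold of at least 2 in both lists, 81.6% of wild-type peaks had a counterpart, so peak strength and place cannot be told apart. The strongest of the 219 without a counterpart lay at SWR1, RRP7, BMS1 (fold 2.76) and UTP9 (2.62), the last 3 being rRNA processing genes, and VMA1, a vacuolar ATPase gene (2.53). No peak lay over SWR1 in swr1Δ, where the gene is deleted. The swr1Δ list added 847 peaks (67.1%), of which, by the same classes, 504 were in gene bodies outside the other places, 181 at other promoters and 72 at tRNA genes, with the strongest at BTN2 (fold 8.14), RPN4, the activator of proteasome genes (6.96), and HSP42 (6.52).

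**Figure D3:**
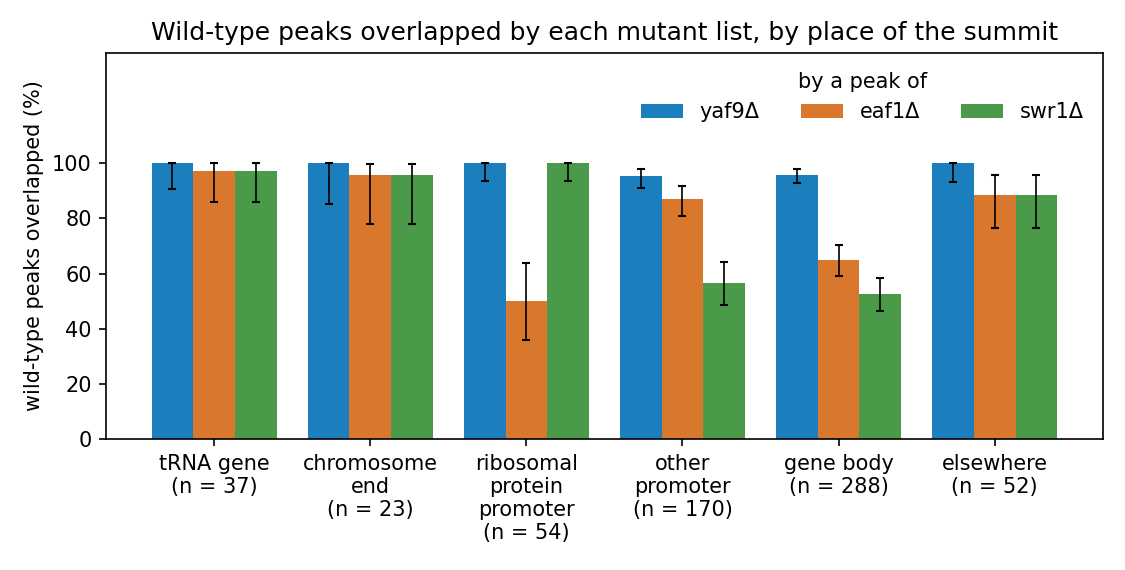
Bars give the percentage of wild-type peaks overlapped by a peak of each mutant list (vertical axis), by the place of the wild-type summit (37 at tRNA genes, 23 at chromosome ends, 54 at ribosomal protein promoters, 170 at other promoters, 288 in gene bodies outside these, 52 elsewhere), and error bars are exact 95% intervals for counting error. At ribosomal protein promoters the eaf1Δ bar stands at 50.0% and the bars of yaf9Δ and swr1Δ at 54 of 54 peaks, and at other promoters the swr1Δ bar stands at 56.5%.

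Across the mutants, 323 of the 625 wild-type peaks (51.7%, interval 47.7–55.7) had a counterpart in all 3 and 5 in none. The strongest shared by all lay at YLL066W-B, RPS23A, RPL13B and beside YML133C. Of the 20 wild-type peaks missing in yaf9Δ, 19 were also missing in swr1Δ, where independent lists would share 7.01, and 14 of the 19 had a peak in eaf1Δ. Missing in both yaf9Δ and eaf1Δ were 5, against 5.06, and in both eaf1Δ and swr1Δ 76, against 55.4. Of the swr1Δ peaks 1242 of 1262 (98.4%, interval 97.6–99.0) overlapped the yaf9Δ list, against 30.2% at random. A longer list overlaps more peaks, and with 625 peaks in each list the share of wild-type peaks with a counterpart fell to 47.4% in yaf9Δ, 33.8% in eaf1Δ and 49.3% in swr1Δ. At shared summits the local background of the lists was correlated (Spearman 0.982 with yaf9Δ, 0.991 with eaf1Δ and 0.992 with swr1Δ, across 368, 310 and 223 peaks, which are not replicates), and the source of this correlation was not tested.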

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

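The tests of gene bodies, background pileup, fragment length and weak peaks below were chosen only after the results they bear on were seen, equal list length was fixed for tRNA genes before the lists were seen and its bound set afterwards, and those of a common background scale, of other promoters, of local background and of the first peaks without ribosomal protein promoters were chosen after the lists were seen but before their own values were.

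Ribosomal protein promoters stood apart in eaf1Δ, where their odds ratio was 0.572, below 1, against 3.84 in yaf9Δ and 8.85 in swr1Δ, and this difference between genotypes was not tested. Shallower libraries in eaf1Δ are argued against by its background pileup of 64.3, against 59.4 in wild type. A loss at promoters of every kind is argued against by the 97 of 108 other wild-type promoter peaks of the same fold range with a counterpart (89.8%, interval 82.5–94.8, against 50.0%, 36.1–63.9), although at or above the median fold of the ribosomal protein peaks only 1 other promoter peak was left to compare, and it had no counterpart. That was the peak at YGL188C-A. Other promoter peaks were classed by their summit alone, so they may still overlap a ribosomal protein promoter. A higher local background in eaf1Δ cannot be told apart from a loss of Swc4, since the median ratio of 0.849 to wild type comes from the 23 ribosomal protein peaks that both lists share, and promoters without an eaf1Δ peak have no background value. A hypothesis for a repeat with replicates is that Swc4 at these promoters may depend on Eaf1, and unspecific signal, growth rate and transcription of these genes were not tested.

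The mutant lists were longer than that of wild type, and most summits in yaf9Δ and eaf1Δ lay in gene bodies. A lower scale of the control is argued against by the 3015 peaks of yaf9Δ and 2580 of eaf1Δ that stayed on the wild-type background scale, and higher coverage by background pileups of at most 1.08 times that of wild type. Fragment length and number cannot be told apart from Swc4 binding, because the shortest peak was 351 bp in wild type and at most 252 bp in the mutants, and fragments per base followed list length (1.81 in yaf9Δ, 1.53 in eaf1Δ, 1.27 in swr1Δ), although eaf1Δ and swr1Δ, with shortest peaks of 249 and 252 bp, had 2937 and 1262 peaks. Weak peaks near the threshold as the source of the gene body summits cannot be judged from a −log10 q of at least 5. That cut kept 4071 of 4522 nuclear peaks in yaf9Δ and 2577 of 2900 in eaf1Δ, so the share could change little. Of the peaks kept, 83.5% in yaf9Δ (interval 82.3–84.6) and 81.2% in eaf1Δ (79.7–82.7) had a summit in a gene body, against 72.9% and 72.8% at random. Among peaks at or above the median −log10 q of their list it was 76.1% in yaf9Δ (74.3–77.9), above random. In eaf1Δ it was 73.4% (71.1–75.7), not set apart from random. At equal list length it was 43.2% in yaf9Δ and 61.4% in eaf1Δ against 62.6% in wild type. The share thus fell towards the top of both lists, and what sets the lower-ranked peaks apart stays open. Whether the missing ribosomal protein promoter peaks account for the higher share among the first 125 peaks of eaf1Δ than of wild type cannot be told. Without such peaks it was 49.6% in eaf1Δ (interval 40.5–58.7) and 40.0% in wild type (31.3–49.1), within the bound of 10 points set before. But leaving them out refills the wild-type peaks from lower ranks, where the share was higher by itself (56.0% at ranks 126 to 250). In yaf9Δ it was 24.0% (16.8–32.5) and in swr1Δ 13.6% (8.13–20.9) without such peaks. The genotype itself stays open.

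More tRNA genes had a peak in the mutants. The length of the lists is argued against for yaf9Δ and swr1Δ, which held 116 and 138 tRNA genes at equal list length against 62 in wild type, and a lower scale of the control by the 149 and 138 on the wild-type background scale. Longer fragments in wild type, with a shortest peak of 351 bp, cannot be told apart from less Swc4 at tRNA genes, because blurring would hide short genes and no value in the lists separates them. Between eaf1Δ and swr1Δ, whose shortest peaks were 249 and 252 bp, the count at equal list length was 85 against 138. A hypothesis is that Swc4 may bind more tRNA genes without Yaf9 or Swr1, and the genotype stays open as untested.

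Mitochondrial DNA, left out of the placement tests and counted only among all peaks and in the overlaps between lists, held 68 peaks in yaf9Δ, 37 in eaf1Δ, 4 in swr1Δ and 0 in wild type. Whether these peaks are unspecific signal, and how much of it the nuclear peaks hold, was not tested.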

How the results depend on the processing

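The gene body test, the common background scale and the alternatives for gene bodies, snRNA and snoRNA genes and shared ribosomal protein promoters were tests chosen only after the results were seen. No paired analysis was possible because each list pools both repeats, and for the same reason a replicate block or leaving out a replicate was not run. Centromeres, replication origins and long terminal repeats were not tested, since the gene table holds none. Of 286 alternative values 213 kept their direction and side of the threshold or stayed close, 29 moved, 20 reversed, 16 became weaker and 8 stronger, and unless the setting itself shows it the cause was not tested. For the placement tests the side was that of the test for more peaks, so a lost call for fewer peaks was not checked. The number of tRNA genes stayed close in 30 of 31 and peaks at tRNA genes in 30 of 32. Gene body ratios in yaf9Δ and eaf1Δ stayed called with −log10 q of at least 5 (1.15 and 1.12) and with merged peaks (1.16 and 1.14). Ribosomal protein odds ratios stayed called in all 6 alternatives in wild type (9.70 to 22.4), yaf9Δ (3.84 to 17.1) and swr1Δ (6.82 to 14.4). With −log10 q of at least 5, ratios at chromosome ends passed the threshold in wild type (1.68) and swr1Δ (1.57), and odds ratios no longer passed for cell wall genes in wild type (3.40) and swr1Δ (4.15) and ribosomal protein genes in eaf1Δ (0.630). With fold of at least 2 fewer peaks remained by construction, 190 in wild type, 1670 in yaf9Δ, 1080 in eaf1Δ and 491 in swr1Δ, with 35, 141, 102 and 136 tRNA genes in the same order. Ends then passed in wild type (3.49) and swr1Δ (2.53) and turned in eaf1Δ (1.31), and gene bodies turned in yaf9Δ (0.936) and eaf1Δ (0.932). The yaf9Δ list overlapped 90.5% of wild-type peaks and swr1Δ 81.6%, and 1492, 942 and 334 peaks of yaf9Δ, eaf1Δ and swr1Δ had no wild-type peak. Cell wall genes lost their call in wild type (2.87) and yaf9Δ (3.54) and ribosomal protein genes in eaf1Δ (0.776), and the histone odds ratio in wild type turned to 0. With equal list length each list held 625 peaks by construction. Ends turned in yaf9Δ (1.53) and eaf1Δ (1.28) and passed in swr1Δ (1.87), gene bodies turned in yaf9Δ (0.593) and eaf1Δ (0.843), and snRNA and snoRNA genes in eaf1Δ (1.75), while in yaf9Δ these passed (5.17), as they did there with fold of at least 2 (1.91). Overlap fell to 47.4% in yaf9Δ, 33.8% in eaf1Δ and 49.3% in swr1Δ, 322, 412 and 316 peaks had no wild-type peak, and cell wall genes lost their call in yaf9Δ (4.39). Ends of 20 kb reversed wild type (0.835) and swr1Δ (0.855), and ends of 5 kb passed in swr1Δ (1.62). Promoters of 250 bp reversed yaf9Δ (0.893) and ended calls for cell wall genes in wild type (3.26) and swr1Δ (3.99), histones in wild type (7.07) and ribosomal protein genes in eaf1Δ (0.696). Promoters of 1000 bp ended the same calls (3.68, 3.76, 5.25 and 0.782). A summit in the promoter reversed yaf9Δ (0.837) and weakened eaf1Δ (1.02). Placement outside protein-coding genes raises the random count in promoters and tRNA genes by construction. It reversed ends in wild type (0.749) and swr1Δ (0.691), tRNA genes in yaf9Δ (0.612) and eaf1Δ (0.649), and promoters in yaf9Δ (0.622), eaf1Δ (0.778) and swr1Δ (0.872). Overlap of 50% of the shorter peak gave 94.9% in yaf9Δ. Summits at most 100 bp apart gave 77.4% in yaf9Δ, 56.6% in eaf1Δ and 47.4% in swr1Δ. On the wild-type background scale yaf9Δ held 3015 peaks. The share of wild-type ribosomal protein promoters with an eaf1Δ peak was 30.6%, and ranged from 4.71% at equal list length to 48.3% with promoters of 1000 bp. Depth per repeat is unknown, so a place without a peak is not shown to lack Swc4.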

Other observations

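The counts of gene body summits below were chosen only after the lists were seen, and no tests were run on them. The gene lists given here were picked after their values were seen. Of 14 translation factor genes 8 had a body summit in wild type, 12 in yaf9Δ, 8 in eaf1Δ and 7 in swr1Δ, and of 19 glycolysis and fermentation genes 6, 18, 13 and 9, while among all protein-coding genes it was 6.55%, 48.8%, 34.9% and 11.6%. Ribosomal protein genes had a body summit in 32.6% of cases in wild type, 73.2% in yaf9Δ, 8.70% in eaf1Δ and 18.1% in swr1Δ. Of 20 chaperone and heat shock genes 2 had a body summit in wild type, 17 in yaf9Δ, 11 in eaf1Δ and 8 in swr1Δ, and of 24 ribosome biogenesis genes it was 5, 14, 2 and 0. Oxidative phosphorylation genes stood at 5.71%, 48.6%, 40.0% and 2.86%, and subtelomeric gene families at 0%, 38.6%, 38.6% and 9.09%. The untagged strain was not analysed here, so how much of this signal comes without a tag is unknown.

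Promoters outside the lists that passed their tests also held Swc4. RNR2, a subunit of ribonucleotide reductase, had a promoter peak in all 4 lists, with a fold of 2.06 in wild type, 3.69 in yaf9Δ, 3.47 in eaf1Δ and 3.60 in swr1Δ. EST3, a telomerase subunit, also had one in all 4 lists, with folds of 1.66, 3.37, 2.24 and 3.15. SPL2, of the phosphate regulon, had folds of 2.27, 5.18, 1.95 and 4.49, and YRF1-6, a helicase gene of the subtelomeres, 4.10, 4.12, 3.26 and 5.76. Folds are those within each list and were not compared between lists.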
